A study of Homo sapiens with 6 samples.

How the data were processed

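RNA-seq was carried out on 6 libraries of Huh7, a human hepatocellular carcinoma line. Per the labels, 3 libraries came from cells with a control short hairpin RNA (shRNA) and 3 from cells with an shRNA against CTSV. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with an NEBNext Ultra II kit for mRNA. Whether the libraries keep strand, the shRNA sequences and the number of shRNAs used are not given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separate cultures.

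One table of all 6 libraries was used. Its per-gene read counts are raw whole-number counts made by the authors, and no normalization is recorded for them. Upstream, per the submitters' processing notes, HISAT2, StringTie and SAMtools were used with the hg38 genome, without versions. The tool that counted reads, the annotation and the treatment of reads with several matches are not given in the sources used here. The table also holds the authors' log2 fold changes, which the values show to be control over knockdown, so that their sign is opposite to the one used here. It further holds the authors' p-values and adjusted p-values, and the testing tool is not given in the sources used here. The deposited adjusted p-values equal a Benjamini-Hochberg adjustment over 16772 unique gene names, with a largest difference of 1.4e-15. For the other 10622 names they are set to 1.

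The deposited table has 28915 entries under 27394 gene names. A total of 127 names stand on more than 1 entry, 1648 entries in all, and no such name has entries that differ in any value. For example, Y_RNA fills 758 entries with the same values. The copies do not measure separate genes, so 1 entry per name was kept and 1521 were removed before any library total was computed. Coordinates are those of the table on hg38. Gene types, transcript lengths and GC content came from GENCODE v29, in which 28805 entries were found by identifier, 97.0% of them with the same start and end.

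Library totals after this step lay between 16258803 and 18106207 counts. The main test was edgeR 4.0.16 in R 4.3.3, its quasi-likelihood test (glmQLFit and glmQLFTest) with TMM normalization, the filterByExpr filter by group, Benjamini-Hochberg adjustment and no covariate. A gene was called at an adjusted p under 0.05, and fold changes are CTSV shRNA over control shRNA. "Rose" and "fell" are used for called genes. The common dispersion corresponds to a biological coefficient of variation of 6.87%, which sets the precision of single-gene values. CPM values are normalised with TMM and given as mean ± SD over 3 libraries.

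A set of 29 gene lists was fixed before the data were examined, covering proteolysis, lysosome and autophagy, cell cycle, hepatocyte functions, metabolism, stress responses, immune genes, adhesion and markers of other liver cell types. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 29 lists. Camera with a correlation estimated from the 6 libraries and the fry test were run beside it. Named genes followed a rule fixed at the same time. It takes CTSV and its closest paralog CTSL, and the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 1, groups that do not overlap and an established symbol. It adds up to 4 called members of each list with the smallest adjusted p and the 4 called genes of highest level. Some genes that the rule names are not reported here.

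The main test was also tested on simulated data drawn from the real means, dispersions and library sizes, with 50 genes changed at each of 4 fold sizes. Over 15613 genes it recovered 32% of genes changed 1.2-fold, 56% at 1.5-fold, 72% at 2-fold and 92% at 3-fold. There were 7 false calls, 5.26% of all calls. Far fewer genes changed there than the 6433 called in the real libraries. The Benjamini-Hochberg cut was therefore stricter, and the recovered shares do not give the sensitivity in the real data. In simulated data without change it called 0 genes and 0 lists, and a simulated list of 25 genes changed 1.3-fold was called. The draws used means, dispersions and library sizes, with no correlation between genes put in. The list results in simulated data therefore cannot test camera's preset correlation, on which the list calls in the real libraries depend. A length trend added to simulated libraries gave 4285 calls, and 0 after the length and GC offsets described next.

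Alternatives fixed before the data were examined were size factors by the RLE method, no low-count filter, a filter at a mean CPM of 1, the replicate number as a block, DESeq2 1.42.0, a fold limit of 2, and leaving out each library in turn. Alternatives added later kept all deposited entries, added loess offsets (span 0.5) for transcript length and GC content, or left out mitochondrial genes. Later additions also include an enterocyte gene list, set against 10000 random lists drawn within 20 bins of mean CPM over all libraries, splits by mean CPM over all libraries (gene lists at 10 CPM and noncoding genes at 0.5 CPM), and the KEGG pathways named in the deposited annotation, of which 306 had 10 to 300 tested genes. Raw reads, isoforms and splicing were not analysed here.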

Results

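RNA-seq libraries of Huh7 cells, a human hepatocellular carcinoma line, were compared between 3 libraries with a control shRNA and 3 with an shRNA against CTSV. CTSV encodes cathepsin V, a lysosomal cysteine protease, and the series design states the aim as following its function in liver cancer. The control libraries held 18106207, 16975502 and 16258803 counts, and the knockdown libraries 16340854, 16280506 and 17930442. The first principal component of log2 CPM took 50.5% of the variance and placed the groups on opposite sides. The p-values below measure only the spread between these libraries, which may be technical.

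CTSV mRNA was lower in each knockdown library than in each control library. The gene (ENSG00000136943) lies on the minus strand of chromosome 9, from 97029679 to 97039643 on hg38, and is annotated as protein coding with 3 transcripts of 5 to 8 exons. Raw counts were 755, 740 and 658 in the controls and 304, 264 and 296 in the knockdown libraries. Normalised levels were 42.6 ± 1.79 and 16.9 ± 1.31 CPM (SD, n = 3 each). CTSV thus fell by 1.34 on the log2 scale (SE 0.0958, adjusted p = 7.2e-14, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), to 0.396 of the control level. The part of the transcript that the shRNA matches is not given in the sources used here. CTSL, the closest paralog, was at 76.0 ± 4.59 CPM in controls and 80.9 ± 11.3 CPM in knockdown libraries (n = 3 each), a log2 fold change of 0.09 with an adjusted p of 0.368 in the same edgeR test. Without knockdown replicate 3 its log2 fold change was 0.20 and passed the edgeR test (adjusted p = 0.0301).

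**Figure D1:**
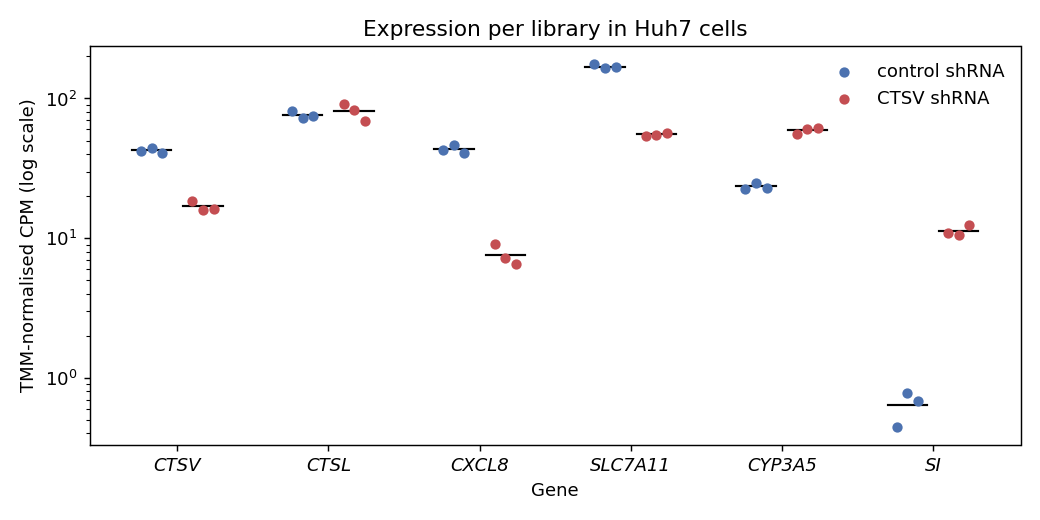
TMM-normalised CPM (log axis) of 6 genes in each of the 3 control shRNA (blue) and 3 CTSV shRNA (red) libraries, with bars at the group means. CTSV, CXCL8 and SLC7A11 lay lower in the knockdown libraries, CYP3A5 and SI lay higher, and CTSL overlapped between the groups.

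In knockdown cells, 20 of 21 NRF2 targets and metallothioneins and 24 of 26 genes of the ER stress and amino acid response fell. So did 16 of 22 cytokine, chemokine and NF-kB feedback genes. In the other direction, 18 of 31 complement and coagulation genes and 12 of 23 cytochrome P450, conjugation and bile acid genes rose. Of 15968 genes tested, 2982 rose and 3451 fell, and 676 of the rises and 153 of the falls were at least 2-fold. The rule named as largest rise SI, the sucrase-isomaltase of the intestinal brush border, at 0.639 ± 0.172 CPM in controls and 11.3 ± 0.998 CPM in knockdown libraries (n = 3 each), a log2 fold change of 4.14 (SE 0.252). HEPH, a ferroxidase of enterocytes, rose by 3.80, PRDM1, a transcriptional repressor, by 3.63 and FOLH1, a folate hydrolase, by 3.05 on the log2 scale. These rises started from low levels. HEPH was at 0.259 ± 0.0463 CPM in controls and 3.69 ± 0.333 CPM in knockdown libraries, and PRDM1 at 0.415 ± 0.117 and 5.25 ± 0.558 CPM (n = 3 each). FOLH1 was at 0.624 ± 0.495 CPM in controls and 5.15 ± 0.822 CPM in knockdown libraries (n = 3 each), and without control replicate 3 its log2 fold change was 3.86. The somatostatin receptor gene SSTR1 rose by 2.82, the membrane mucin gene MUC13 by 2.68 and the adenylyl cyclase gene ADCY5 by 2.39. SSTR1 was at 0.573 ± 0.184 CPM in controls and 4.095 ± 0.947 CPM in knockdown libraries (n = 3 each). The fibrillar collagen genes COL11A1 and COL2A1 rose by 2.58 and 2.41. ACTN3, a sarcomeric alpha-actinin, rose by 2.44 from 25.3 ± 0.803 to 137.1 ± 3.17 CPM (n = 3 each), the highest level among these 10.

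The neutrophil chemokine gene CXCL8 had the most negative log2 fold change under the rule, -2.51 (SE 0.116), from 43.2 ± 3.0 to 7.59 ± 1.29 CPM (n = 3 each). GDF15, a stress-induced cytokine, had a log2 fold change of -1.85, from 95.1 ± 7.96 to 26.4 ± 0.895 CPM (n = 3 each). The transcription factor gene NFIX (-2.06), the calcium-binding protein genes TESC (-1.96) and S100A9 (-1.93), the stress regulator NUPR1 (-1.91), the metallothionein gene MT2A (-1.90) and the small GTPase gene RASD1 (-1.83) also fell. RN7SL2, a signal recognition particle RNA, had a log2 fold change of -1.94, from 10.8 ± 6.81 to 2.83 ± 1.06 CPM (n = 3 each), which was -1.29 without control replicate 1. The called genes of highest level were the mitochondrial MT-CO1 (0.31), MT-RNR2 (0.51) and MT-ND4 (0.27) and the albumin gene ALB (0.22), all higher in knockdown libraries.

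**Figure D2:**
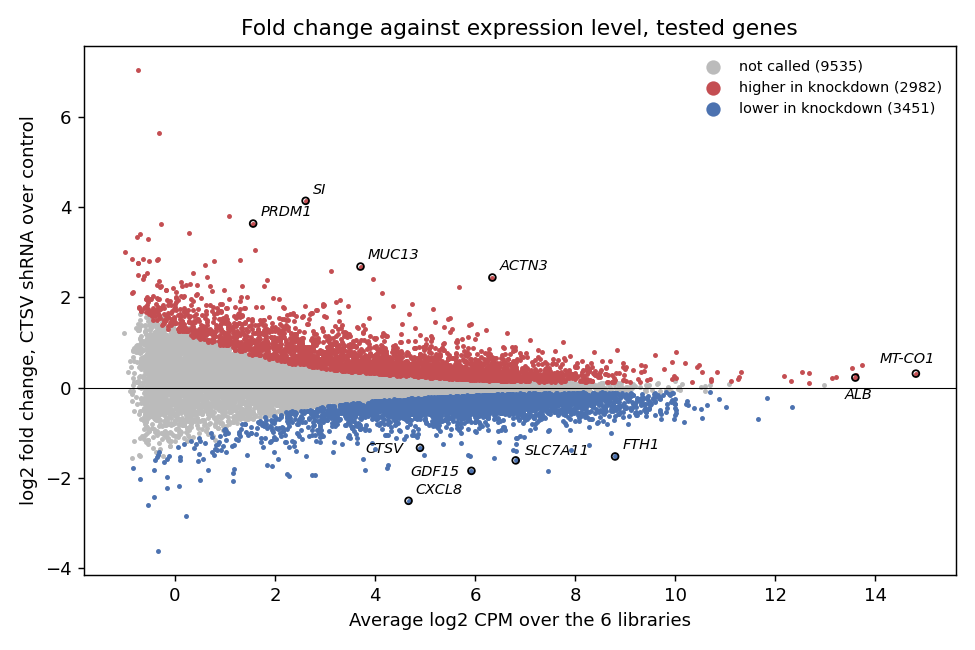
Log2 fold change (CTSV shRNA over control shRNA) against average log2 CPM over the 6 libraries for the 15968 tested genes, one point per gene. Red points are the 2982 genes that rose, blue points the 3451 that fell and grey points genes not called, with 11 named genes circled.

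Library composition moved with the groups as well. Mitochondrial genes took 9.23% ± 0.245 of counts in controls and 11.6% ± 0.208 in knockdown libraries (SD, n = 3 each). Long intergenic noncoding RNA genes took 0.523% ± 0.0231 and 0.693% ± 0.0118, antisense genes 0.321% ± 0.00411 and 0.415% ± 0.00275, and processed pseudogenes 0.576% ± 0.0199 and 0.447% ± 0.0152. In each of these the groups did not overlap, and an exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.1. Among tested genes, 172 of 800 lincRNA genes rose and 17 fell, as did 158 and 17 of 876 antisense genes, while 2362 of 12658 protein-coding genes rose and 3312 fell. Gene names below the count filter took 0.141% ± 0.003 of counts in controls and 0.193% ± 0.0026 in knockdown libraries (SD, n = 3 each). Antisense genes are uncertain because strand use in counting is not stated.

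Genes of oxidative defence and of the amino acid and ER stress response fell nearly throughout. Among 21 tested NRF2 targets and metallothioneins, 20 fell, 0 rose and 1, NFE2L2 itself (-0.11), was not called. Adjusted over the list alone, all 21 fell. The glutathione synthesis subunit gene GCLM had a log2 fold change of -1.10, the thioredoxin reductase gene TXNRD1 -0.77, the pentose phosphate enzyme gene PGD -0.81 and the ferritin heavy chain gene FTH1 -1.53. The list's median was -0.77 (camera adjusted p = 1.1e-11, and adjusted p = 0.15 with an estimated correlation). In the ER stress and amino acid response list, 24 of 26 tested members fell, 1 rose and 1 was not called, with equal counts adjusted over the list alone. These included the cystine transporter gene SLC7A11 (-1.61), its partner SLC3A2 (-0.94), the secreted glycoprotein gene STC2 (-1.25) and the pseudokinase gene TRIB3 (-0.97). The median was -0.70 (camera adjusted p = 4.9e-12, and adjusted p = 0.15 with an estimated correlation).

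Most tested cytokine, chemokine and NF-kB feedback genes fell, and most interferon-stimulated genes were not called. Among 22 tested cytokine, chemokine and NF-kB feedback genes, 16 fell, 0 rose and 6 were not called, with the same counts adjusted over the list alone. Besides CXCL8, the chemokine genes CXCL5 (-1.50) and CCL20 (-1.40) and the adhesion molecule gene ICAM1 (-0.95) fell. The median was -0.67 (camera adjusted p = 1.4e-05, and adjusted p = 0.15 with an estimated correlation). Among 26 tested interferon-stimulated genes, 8 rose, 2 fell and 16 were not called, against 8 and 1 adjusted over the list alone. SAMD9 (1.47), the RNA sensor gene DDX58 (0.70) and the signal transducer STAT2 (0.50) rose, and MX2 fell (-0.31). The interferon list was not called (camera adjusted p = 0.06), but it was without control replicate 1 (0.048), without knockdown replicate 3 (0.028), without a filter on low counts (0.034) and with length and GC offsets (0.015). Its 6 members with a mean of 10 CPM or more over all libraries had a median of 0.04, with 2 higher and 2 lower, and the 20 below it a median of 0.47, with 6 higher and 0 lower, against 0.26 for all tested genes below it. Of 22 tested genes of antigen presentation and immune checkpoint ligands, 2 rose, 5 fell and 15 were not called, with equal counts adjusted over the list alone. HLA-DMA (1.73) rose, and the NKG2D ligand gene ULBP1 (-1.75) and the adhesion gene NECTIN2 (-0.23) fell. HLA-DMA was at only 0.435 ± 0.0137 CPM in controls and 1.46 ± 0.184 CPM in knockdown libraries (n = 3 each). The median of this list was -0.01 and its mean 0.03, with the camera direction down and an adjusted p of 0.97.

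In several groups of liver-function genes, more members rose than fell. Among 31 tested complement and coagulation genes, 18 rose, 2 fell and 11 were not called, against 19 and 3 adjusted over the list alone. The serpin genes SERPIND1 (0.83) and SERPINF2 (0.89) and the coagulation factor genes F5 (0.54) and F12 (1.01) rose. The median was 0.27 (camera adjusted p = 0.0014, and adjusted p = 0.15 with an estimated correlation). Among 23 tested cytochrome P450, conjugation and bile acid genes, 12 rose, 3 fell and 8 were not called, with equal counts adjusted over the list alone. The drug-metabolising enzyme gene CYP3A5 (1.34), the sulfotransferase gene SULT2A1 (0.67) and the canalicular transporter gene ABCC2 (0.33) rose. The median was 0.38 (camera adjusted p = 0.024, and adjusted p = 0.16 with an estimated correlation). This call was also lost without control replicate 1 (camera adjusted p = 0.056) and at a mean CPM of at least 1 (0.066). The 8 members with a mean of 10 CPM or more over all libraries had a median of 0.12, with 4 higher and 2 lower, and the 15 below it a median of 0.64, with 8 higher and 1 lower. In the complement and coagulation list, the 20 members at or above that level had a median of 0.21 and the 11 below it 0.58, and all tested genes below it had a median of 0.26.

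Of 31 tested hepatocyte secreted proteins and transcription factors, 14 rose, 6 fell and 11 were not called, with equal counts adjusted over the list alone. The alpha-fetoprotein gene AFP (0.44), the transferrin gene TF (0.54) and the apolipoprotein gene APOH (1.02) rose, and the transcription factor gene CEBPB (-0.97) fell. The list's median was 0.10 and it was not called (camera adjusted p = 0.1). Among 7 tested cystatin-family inhibitors, 3 rose, 2 fell and 2 were not called, with equal counts adjusted over the list alone. The plasma protein genes AHSG (0.45), KNG1 (0.87) and HRG (1.85) rose and the intracellular inhibitor gene CSTB (-0.41) fell, with a median of 0.28 and a camera adjusted p of 0.38. Without control replicate 3, HRG had a log2 fold change of 2.49.

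Other lysosomal genes moved in both directions. Among 13 tested cathepsin genes other than CTSV, 3 rose, 1 fell and 9 were not called, with equal counts adjusted over the list alone. CTSF (0.60), CTSK (0.57) and CTSB (0.25) rose and CTSC fell (-0.14), with a list median of 0.05 and a camera adjusted p of 0.8. On chromosome 11, CTSF starts at 66563463, next to ACTN3, which ends at 66563329 and rose by 2.44. The CTSF value is uncertain because strand use in counting is not stated. The fall of CTSC was not called without knockdown replicate 1 (adjusted p = 0.0673, edgeR's quasi-likelihood test). Among 31 tested genes of lysosomal membrane, hydrolases and acidification, 4 rose, 11 fell and 16 were not called, against 4 and 12 adjusted over the list alone. The hydrolase genes ASAH1 (-0.60), NEU1 (-0.54) and GLA (-0.71) fell. The median was -0.08 and the list was not called (camera adjusted p = 0.089). It was called without control replicate 3 (camera adjusted p = 0.044), without a filter on low counts (0.013), with DESeq2 (0.017) and with all deposited entries kept (0.03). Of 24 tested autophagy genes, 3 rose, 7 fell and 14 were not called, against 3 and 8 adjusted over the list alone. The cargo receptor gene SQSTM1 (-1.01), MAP1LC3B (-0.37) and WIPI1 (-0.61) fell and the kinase gene ULK1 rose (0.54), with a median of -0.09 and a camera adjusted p of 0.21.

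In both cell cycle lists, more genes fell than rose, by small amounts. Among 29 tested G1/S and DNA replication genes, 12 fell, 4 rose and 13 were not called, against 13 and 4 adjusted over the list alone. The cyclin D1 gene CCND1 (-0.88) and CDK4 (-0.67) fell, while the helicase subunit gene MCM6 (0.53) and CDK6 (0.38) rose. The median was -0.15 (camera adjusted p = 0.0067, and adjusted p = 0.18 with an estimated correlation). Length and GC offsets also ended this call (camera adjusted p = 0.054). Among 30 tested G2/M and mitosis genes, 16 fell, 1 rose and 13 were not called, against 17 and 1 adjusted over the list alone. The mitotic kinase gene AURKA (-0.56), the spindle factor gene TPX2 (-0.40) and the checkpoint genes CDC20 (-0.36) and BUB1B (-0.33) fell. The median was -0.18 (camera adjusted p = 0.0033, and adjusted p = 0.15 with an estimated correlation). All tested protein-coding genes had a median of -0.03. A mean of 10 CPM or more was reached by 26 of the 29 and 29 of the 30 members, and no median of all genes at that level was computed.

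Of 20 tested Wnt/beta-catenin, YAP and MYC targets, 8 fell, 1 rose and 11 were not called, against 8 and 2 adjusted over the list alone. MYC itself (-0.72), the nucleolar protein genes NPM1 (-0.60) and NCL (-0.49) and the YAP target ANKRD1 (-1.11) fell. The Wnt/beta-catenin members AXIN2 (-0.28), NOTUM (-0.49), RNF43 (0.31), ZNRF3 (0.10) and TCF7 (0.01) were not called, so the list's falls do not speak for Wnt targets. The 1 member that rose is not among the genes named here. The median of the whole list was -0.38 (camera adjusted p = 0.0014, and adjusted p = 0.15 with an estimated correlation). Among 21 tested p53 targets, 7 fell, 2 rose and 12 were not called, with equal counts adjusted over the list alone. The antiproliferative gene BTG2 (-1.13) and the apoptosis genes BBC3 (-1.08) and AEN (-0.68) fell and TP53INP1 rose (0.45), with a median of -0.16 and a camera adjusted p of 0.089. Among 10 tested replication-dependent histone genes, 1 rose, 2 fell and 7 were not called, with equal counts adjusted over the list alone. HIST1H2BK (-0.35) and HIST1H1C (-0.18) fell and HIST1H2BD (0.27) rose, with a median of 0.10 and a camera adjusted p of 0.81. Without control replicate 1, HIST1H2BD and HIST1H1C were not called (adjusted p = 0.0895 and 0.136, edgeR's quasi-likelihood test), nor was HIST1H1C without control replicate 2 or knockdown replicate 2 or 3 (0.114, 0.12 and 0.155).

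More glycolysis genes fell than rose, while lipid genes moved both ways. Among 26 tested glycolysis and hypoxia-responsive genes, 13 fell, 3 rose and 10 were not called, against 14 and 3 adjusted over the list alone. The glycolytic enzyme genes GAPDH (-0.62), PKM (-0.54), ENO1 (-0.54) and HK2 (-0.62) fell. The median was -0.27 (camera adjusted p = 0.0024, and adjusted p = 0.16 with an estimated correlation). In the cholesterol synthesis and uptake list, 7 of 24 tested members rose, 6 fell and 11 were not called, with equal counts adjusted over the list alone. The synthesis genes HSD17B7 (0.63), DHCR7 (-0.30) and CYP51A1 (-1.23) were its examples, with a median of -0.01 and a camera adjusted p of 0.97. In the fatty acid synthesis and lipid storage list, 6 of 23 tested members rose, 8 fell and 9 were not called, with equal counts adjusted over the list alone. The lipid droplet gene PLIN2 (-0.90) and the elongase gene ELOVL5 (-0.41) fell, and the carboxylase gene ACACB (1.03) and ELOVL6 (0.43) rose, with a median of 0.08 and a camera adjusted p of 0.97. In the fatty acid oxidation list, 6 of 23 tested members rose, 6 fell and 11 were not called, with equal counts adjusted over the list alone. The binding protein gene FABP1 (0.60) and EHHADH (0.53) rose and the acyl-CoA synthetase gene ACSL1 (-0.82) and ETFA (-0.32) fell, with a median of 0.02 and a camera adjusted p of 0.89.

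More mesenchymal genes fell than rose, and epithelial adhesion genes divided evenly. Among 17 tested mesenchymal and EMT regulator genes, 9 fell, 3 rose and 5 were not called, with equal counts adjusted over the list alone. The growth factor gene TGFB2 (-0.96) and the vimentin gene VIM (-0.42) fell, and the integrin gene ITGA5 rose (0.39). The other rises were FN1 (0.09) and CDH2 (0.13), and ZEB1 (-0.02), ZEB2 (-0.90) and CD44 (0.09) were not called. The 12 members with a mean of 10 CPM or more over all libraries had a median of -0.18, with 7 lower and 3 higher. The 5 below it had a median of -0.88, with 2 lower and 0 higher. The median of the whole list was -0.28 (camera adjusted p = 0.0067, and adjusted p = 0.25 with an estimated correlation). Among 16 tested epithelial adhesion and keratin genes, 5 rose, 5 fell and 6 were not called, against 5 and 6 adjusted over the list alone. The E-cadherin gene CDH1 (0.78) and EPCAM (1.08) rose and the keratin genes KRT8 (-0.69) and KRT18 (-0.74) fell. Their list had a median of -0.06 but a mean of 0.13, with the camera direction down and an adjusted p of 0.81. Of 18 tested extracellular matrix and matrix protease genes, 5 rose, 4 fell and 9 were not called, with equal counts adjusted over the list alone. The laminin gene LAMA5 (0.46) and the collagen genes COL1A2 (1.02) and COL6A1 (0.53) rose and the sheddase gene ADAM17 (-0.46) fell, with a median of 0.11 and a camera adjusted p of 0.61.

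Of 13 mitochondrially encoded mRNAs, 8 rose, 0 fell and 5 were not called, against 9 rises adjusted over the list alone. MT-CO1, MT-ND4, MT-ND5 (0.32) and MT-CYB (0.34) were among the rises. The median was 0.19 (camera adjusted p = 0.016, and adjusted p = 0.51 with an estimated correlation). The call was also lost without control replicate 3 (camera adjusted p = 0.073), without knockdown replicate 1 (0.087), with length and GC offsets (0.07) and with all deposited entries kept (0.053).

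Markers of other liver cell types did not move together. Of 6 tested stellate cell, fibroblast and smooth muscle markers, 2 rose, 0 fell and 4 were not called, against 1 rise adjusted over the list alone. The receptor gene PDGFRA rose (1.81) and so did the proteoglycan gene LUM (0.21), with a median of 0.20 and a camera adjusted p of 0.38. LUM was near the threshold (adjusted p = 0.0489, edgeR's quasi-likelihood test), and leaving out control replicate 1, 2 or 3 or knockdown replicate 1 or 3 ended its call (0.0936, 0.168, 0.0568, 0.259 and 0.0627). The 2 tested endothelial markers were not called, nor adjusted over the list alone, with a median of 0.26 and a camera adjusted p of 0.81. Of 4 tested leukocyte markers, the lysozyme gene LYZ (-0.42) fell and 3 were not called, with equal counts adjusted over the list alone, a median of -0.48 and a camera adjusted p of 0.09. Of 9 tested cholangiocyte and progenitor markers, 1 rose, 4 fell and 4 were not called, against 2 and 4 adjusted over the list alone. The annexin gene ANXA4 (0.80) rose and SPP1 (-0.93), SOX4 (-0.28) and SOX9 (-0.17) fell. This list had a median of -0.12 but a mean of 0.09, with the camera direction down and an adjusted p of 0.83. The fall of SOX9 was not called without knockdown replicate 3 (adjusted p = 0.0525, edgeR's quasi-likelihood test).

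**Figure D3:**
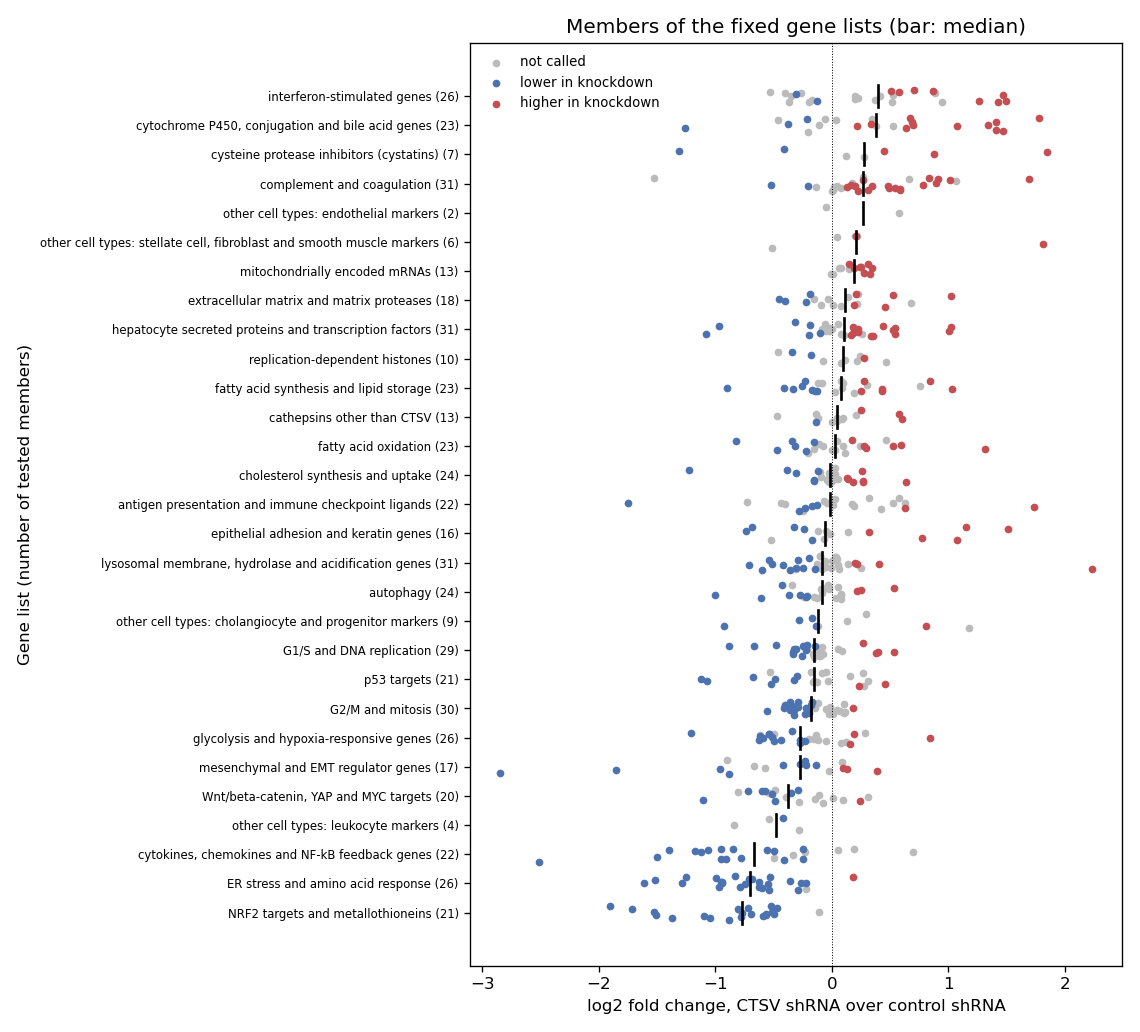
Log2 fold change (CTSV shRNA over control shRNA) of each tested member of the 29 gene lists, one point per gene, with a bar at each list's median and lists ordered by median. Red points rose, blue points fell and grey points were not called, and the NRF2 target and ER stress lists lie lowest, with medians of -0.77 and -0.70.

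Camera called 11 of the 29 lists, 3 higher and 8 lower. None kept its call with a correlation estimated from the 6 libraries, where 8 lists had an unadjusted p under 0.05, while fry called 20 lists in 1 direction. Genes with near-identical copies, including RN7SL2, FTH1, KRT8, KRT18, GAPDH, NPM1, the histone genes and the mitochondrial genes, are uncertain because the treatment of shared reads is not given in the sources used here.

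The authors' deposited table calls 5502 gene names at an adjusted p under 0.05, with 2332 higher and 3170 lower in knockdown cells, of which 533 and 140 are at least 2-fold. Of the 5473 that were also tested here, 5447 were called by edgeR too, and all 5447 had the direction given in the authors' deposited table. A further 986 genes were called here only. In the authors' deposited table CTSV has a log2 fold change of 1.35, control over knockdown, with an adjusted p of 5.36e-31. DESeq2 run here on the counts gave CTSV -1.35, knockdown over control (adjusted p = 5.29e-31, Wald test), with 2335 genes higher and 3181 lower. These values lie close to the deposited ones, so the authors' statistics may come from that tool. The shared calls compare fits of the same libraries and are no independent evidence.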

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

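Among the tests in this part, the fit with length and GC offsets and the split of noncoding genes at a mean of 0.5 CPM were chosen only after the gene calls had been seen. The other tests of the share of low-abundance and noncoding genes address a pattern seen in the data. They are not among the alternatives fixed before the data were examined.

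Gene names below the count filter, which are outside the 15968 genes tested, took more counts in knockdown libraries. These 11426 names held 0.193% ± 0.0026 of counts in knockdown libraries against 0.141% ± 0.003 in control libraries (SD, n = 3 each), and the groups did not overlap. Tested lincRNA genes had a median log2 fold change of 0.34 (95% bootstrap interval 0.292 to 0.378) and tested antisense genes 0.36 (0.319 to 0.395), against -0.03 (-0.0353 to -0.0185) for protein-coding genes. These and all later bootstrap intervals come from 2000 draws of genes, not of libraries. They treat genes as independent and do not measure the spread between libraries.

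For this higher share of low-abundance and noncoding genes, the tables argue against a difference in sequencing depth. With every library thinned to 16258803 counts in 20 draws, the lowest knockdown library still had 747 more detected gene names than the highest control library. Genomic DNA in the knockdown libraries, which would add reads to silent genes of any kind, stays open as part of the cause. The gain in CPM per kb of untested processed pseudogenes was 0.745 of that of untested noncoding RNA genes (95% bootstrap interval 0.604 to 0.903). This ratio cannot single out DNA, because a general rise of low-abundance genes would raise both kinds too. Of 520 tested processed pseudogenes, 42 rose and 66 fell, with a median of -0.06 (-0.124 to 0.000155). Genomic DNA is argued against as the whole cause for the 1772 lincRNA and antisense genes at a mean of 0.5 CPM or more over all libraries. Their median log2 ratio was 0.333 and stayed at 0.266 (0.226 to 0.303) once the gain per kb of noncoding RNA genes under that mean was taken off. More unspliced RNA also stays open: 137 tested sense intronic genes had a median of 0.29 (0.207 to 0.411), which lies above 0 but not above that of lincRNA genes, and a biological effect of the knockdown on noncoding RNA was not tested separately.

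The joint fall in the lists of NRF2 targets, of the ER stress and amino acid response and of cytokine, chemokine and NF-kB feedback genes is the other pattern weighed here. A trend in transcript length and GC content is argued against, because 59 of the 60 members that fell, or 98.3%, were also called lower with length and GC offsets, and their median went from -0.788 to -0.793. Lower CTSV, an effect of the shRNA on other transcripts, or a difference in cell density or nutrient supply between the cultures could each lie behind it. These stay open as hypotheses and were not tested, since each of them would follow the 2 groups.

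For the count of called genes, 3 against 3 libraries make 10 splits, too few for a share of splits under 0.05. The real split gave 6433 genes with edgeR and 7558 at an unadjusted p under 0.05. It was the 1 split with as many, and the highest of the others gave 0 with edgeR, with 162 to 345 genes at an unadjusted p under 0.05. Each of the others mixes control and knockdown libraries on both sides. The group difference then enters their spread, so low counts follow by construction and the contrast does not argue against a chance split.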

How the results depend on the processing

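Keeping all deposited entries, the length and GC offsets and leaving out mitochondrial genes were chosen only after the data had been seen, and all other alternatives before. No result changed direction once called, in any alternative. CTSV kept its call throughout, with log2 fold changes from -1.30 to -1.40 when 1 library was left out. Calls numbered 2980 higher and 3449 lower with RLE size factors, 2743 and 3520 without a filter, 2984 and 3412 at a mean CPM of at least 1, and 2335 and 3181 with DESeq2. They numbered 2445 to 2720 and 3041 to 3202 without 1 library, 3453 and 3910 with all deposited entries, 2773 and 3850 with length and GC offsets, and 2961 and 3500 without mitochondrial genes. Limiting them to at least 2-fold left 676 and 153, by construction. The median log2 fold change of all tested genes was 0.02 with either scaling. Alternatives on FPKM values were not run, since counts were used.

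The numbers of the libraries do not pair them: deviations of same-numbered libraries correlated at -0.012, -0.0025 and 0.021, within the range of all cross-group pairs (-0.033 to 0.034). With the replicate number as a block, 2996 genes were higher and 3490 lower, and 11 lists were called.

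With an estimated correlation, camera called 0 lists, and 8 had an unadjusted p under 0.05. The adjusted p was then 0.18 for G1/S genes, 0.25 for mesenchymal genes, 0.16 for cytochrome P450 genes and for glycolysis, 0.51 for mitochondrial mRNAs, and 0.15 for G2/M, complement and coagulation, cytokines, ER stress, NRF2 targets and Wnt, YAP and MYC targets. Fry does not compare a list with other genes. It called 20 lists in 1 direction, among them cystatins (adjusted p = 0.014), lysosomal genes (0.018), autophagy (0.017), p53 targets (0.00033), extracellular matrix (0.0025), hepatocyte genes (0.0016), interferon-stimulated genes (0.00033), stellate cell markers (0.01) and leukocyte markers (0.0081). Its mixed test, for change in either direction, called 28. These include cathepsins (0.0011), cystatins (3e-05), lysosomal genes (8.5e-06), autophagy (3.8e-05), p53 targets (2.1e-05), epithelial genes, extracellular matrix, hepatocyte genes and interferon-stimulated genes (2.8e-06 each) and cholesterol genes (5.8e-05). They also include fatty acid synthesis (6.1e-06), fatty acid oxidation (3.8e-05), antigen presentation (2.1e-05), histones (0.0021), stellate cell markers (6.6e-05), leukocyte markers (0.0028) and cholangiocyte markers (3.3e-06).

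For camera, the cytochrome P450 list lost its call at a mean CPM of at least 1 (adjusted p = 0.066) and with all deposited entries (0.055). Mitochondrial mRNAs lost theirs with all deposited entries (0.053) and with length and GC offsets (0.07), and G1/S genes with those offsets (0.054). Without a filter, the lysosomal (0.013), autophagy (0.036), p53 (0.013) and interferon (0.034) lists were called. So were the lysosomal (0.017) and hepatocyte (0.0016) lists with DESeq2, the lysosomal list with all deposited entries (0.03), and the hepatocyte and interferon lists with length and GC offsets (0.015 each). Leaving out 1 library gave 0.01 to 0.056 for the cytochrome P450 list, 0.028 to 0.087 for interferon-stimulated genes, 0.044 to 0.2 for lysosomal genes and 0.0029 to 0.087 for mitochondrial mRNAs. For CTSL it gave log2 fold changes of -0.00628 to 0.20. Over the alternatives tested with camera, which leaves out fry, the adjusted p of these lists spanned 0.0095 to 0.16 (cytochrome P450), 3e-05 to 0.51 (mitochondrial), 0.00065 to 0.18 (G1/S), 0.013 to 0.59 (lysosomal), 0.036 to 0.51 (autophagy), 0.013 to 0.24 (p53), 0.015 to 0.19 (interferon) and 0.0016 to 0.37 (hepatocyte). Fewer libraries or another set of genes enter some of these fits, and for the other changes of call the cause was not tested. Named genes that lost their call in some alternative were LUM, HIST1H1C, HIST1H2BD, CTSC and SOX9. In the simulation, 32% of 1.2-fold changes were recovered, under a stricter cut than the one 6433 called genes give in the real data. The share missed in the real data is not known, and small differences among genes not called may stay undetected.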

Other observations

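The enterocyte list, its comparison with lists matched on mean expression, the split by level and the KEGG pathways reported in this part were chosen only after the gene calls had been seen.

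In the KEGG pathways of the deposited annotation, 104 of 127 tested Ribosome genes fell and 1 rose, with a median log2 fold change of -0.45 (camera adjusted p = 1.1e-17, and adjusted p = 0.38 with an estimated correlation). The median was -0.42 with length and GC offsets (camera adjusted p = 3e-13). Ribosomal protein genes share reads with many pseudogenes, so their values are uncertain. Of 72 tested genes of ribosome biogenesis, 43 fell and 2 rose, with a median of -0.30 (camera adjusted p = 2.4e-08, and adjusted p = 0.17 with an estimated correlation). Of 41 tested Proteasome genes, 30 fell and 0 rose, with a median of -0.36 (camera adjusted p = 2.1e-07, and adjusted p = 0.29 with an estimated correlation). Camera did not call Ubiquitin mediated proteolysis (adjusted p = 0.093, and 0.016 with length and GC offsets, where it was called lower), animal autophagy (0.35 and 0.15) or Lysosome (0.81 and 0.78).

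Among 104 tested genes of Oxidative phosphorylation, 59 fell and 3 rose, with a median of -0.28 (camera adjusted p = 2e-06, and adjusted p = 0.45 with an estimated correlation). Of the 13 mitochondrially encoded mRNAs, 8 rose, more than the 3 rises in this set. The set therefore leaves some of them out and does not stand for the mitochondrially encoded part of the pathway. In the pathway of drug metabolism by cytochrome P450, 24 of 42 tested genes rose and 4 fell, with a median of 0.50 (camera adjusted p = 0.0012, and adjusted p = 0.29 with an estimated correlation). Its 20 members at a mean of 10 CPM or more had a median of 0.15 and the 22 below it 0.72. Of the 306 pathways tested, camera called 62, with 8 higher and 54 lower. With an estimated correlation it called 0, and 52 had an unadjusted p under 0.05. The pathways called lower were not set against genes of matched mean expression.

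SI, HEPH and MUC13, which are typical of intestinal epithelium, were among the largest rises, and the hypothesis that other enterocyte genes rose with them was tested on a list of 40 enterocyte and brush border genes written without those seen among the rises. Of its 26 tested members, 20 rose, 1 fell (TM4SF5, -0.25) and 5 were not called. The median log2 fold change was 0.905 (95% bootstrap interval over genes 0.502 to 1.22, camera p = 2.9e-07, and p = 0.0048 with an estimated correlation). The size depended on the level of the members. The 12 with a mean of 10 CPM or more over all libraries had a median of 0.546 (95% bootstrap interval 0.00907 to 0.946), with 9 higher and 1 lower, and the 14 below it a median of 1.32 (0.725 to 1.65), with 11 higher and 0 lower. All tested genes below 10 CPM had a median of 0.262, so part of the larger value may come from the higher share of low-abundance genes in knockdown libraries. As the whole cause this is argued against, because the list's median lay 0.872 above that of 10000 random lists matched on mean expression, of which 0 reached it and whose medians had a middle 95% of -0.153 to 0.23. Examples are the intestinal transcription factor genes CDX2 (5.45 CPM in controls and 13.4 CPM in knockdown libraries) and ISX (2.41 and 7.64 CPM), and the brush border genes MEP1A (89.4 and 184.6 CPM), ANPEP (60.4 and 138.5 CPM) and VIL1 (253.1 and 351.3 CPM). Control cells already expressed 12 of the 26 at 10 CPM or more, and 0 of the 26 are in the fixed lists. The random lists were matched on mean expression only. They cannot tell an intestinal-type programme from a wider rise that includes liver-function genes, such as the complement and cytochrome P450 lists. An intestinal-type programme may be higher in the knockdown cells, as a hypothesis found and tested on the same libraries. Whether it follows from lower CTSV or from a difference between the cell lines was not tested.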
